A study of Homo sapiens with 2 samples.

How the data were processed

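Chromatin immunoprecipitation followed by sequencing was carried out in NB4 cells, an established acute promyelocytic leukemia line that carries the PML-RARA fusion. There were 2 libraries, 1 for each of 2 antibodies raised against different parts of GFI1, a zinc-finger repressor of transcription in blood cells. The antibodies are named here by their catalogue numbers, ab21061 and sc8558. Neither antibody had a replicate, and the labels do not say whether the libraries came from separate cultures.

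Some labels disagree with each other. The protocol describing the immunoprecipitation names antibodies against the PML/RARα fusion protein, whereas the antibody labels and the stated design name GFI1. The title of the sc8558 sample reads GFI2, whereas its antibody label reads GFI1. The antibody labels were followed.

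Per the submitters' processing notes, Bowtie2 2.2.9 and MACS 1.4.2 were used with the hg38 build. The options of either tool, any filter on reads and the control used for peak calling are not given in the sources used here. The deposited score of each peak is the authors' own value from the peak caller, which on the MACS scale is a multiple of the negative logarithm of a p-value. It ran from 50.01 to 3100 in both lists, and 2 peaks of each list stood at 3100. Scores were used to describe, rank or filter peaks within a list and to correlate ranks across overlapping pairs, and their levels are not comparable between the libraries. Peaks were listed per library, not on pooled libraries. The sequencing depth is unknown and no control library was analysed here.

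All 7687 and 7562 peaks lay on the primary chromosomes. Overlap was counted from 1 bp. Shared regions were made by merging overlapping peaks of the 2 lists. Random expectation came from 1000 sets of peaks (200 for alternatives) placed at random on their own chromosomes with their widths kept. Exact Clopper-Pearson 95% intervals are given for shares, Newcombe intervals for differences of shares and intervals from 1000 bootstrap samples for rank correlations. They cover counting error only, and no p-value between antibodies was computed. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

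Several planned steps could not be run as fixed before the data were examined. The gene table used, from RefSeq on the same build, gave gene starts, ends and types but no strand, exons or sequence. Transcription start sites were therefore replaced by either end of a protein-coding gene (20037 genes), so a peak near an end may lie at the start or at the finish of a gene. Exons and introns were not separated, assembly gaps were not excluded from random placement, and the 18 planned sequence motifs were not searched. Random gene lists were not matched on GC content.

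For 16 gene lists fixed before the data were examined (12 lists of symbols and 4 families defined by name), the number of members with a shared region within 1 kb of an end was set beside 10000 random lists of the same size. A list was said to stand apart when its count lay outside the central 99% of random lists. For gene lists, the random range named below is this central 99%, and single random lists could lie beyond it. The comparison describes these libraries and is not corrected for the 16 lists, of which chance would place at most 0.16 apart. Some genes, such as GFI1, belong to more than 1 list.

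The genes named were fixed by rule: the 10 shared regions with the best worse rank, the 5 highest-scoring peaks of each antibody without overlap, up to 4 members of each list with a shared region within 1 kb, and GFI1, GFI1B, PML and RARA. Regions are named by the protein-coding gene with the nearest end. Of the ab21061 peaks this rule names, 2 are not reported here. On simulated data for the 7687 peaks, planted overlaps of 0, 30 and 60% were recovered as 0.442, 30.3 and 60.3%. Planted peaks were copies moved by less than the width of the narrowest peak, so their overlap was certain and only the counting was checked. Simulated lists of 38 genes were called above in 0.4% of cases with no planted member and in 62.2% with 4 planted members.

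Alternatives fixed beforehand were a score of 100 or more, lists of equal length, stricter overlap, wider windows around gene ends and ends of all gene types. Alternatives chosen after seeing the data were leaving out the longest stretch of each chromosome without an annotated gene, random lists matched on gene length or moved along the gene order, whole gene spans with 10 kb on either side (also at a score of 100 or more), each antibody alone, high-scoring peaks against the full other list, and the share inside genes at a score of 100 or more.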

Results

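Chromatin from NB4 cells was immunoprecipitated with 2 antibodies labelled as raised against different parts of GFI1, 1 library each. The ab21061 list held 7687 peaks with a median width of 776 bp, covering 6.68 Mb. The sc8558 list held 7562 peaks with a median width of 746 bp, covering 6.31 Mb. Median scores were 82.4 and 81.7, and 2901 and 2831 peaks had a score of 100 or more. Depth is unknown, and without replicates the values below describe these 2 libraries.

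The question set by the design was how far the 2 antibodies marked the same places. Of the ab21061 peaks, 4896 (63.7%, 95% interval 62.6 to 64.8) were overlapped by an sc8558 peak. Of the sc8558 peaks, 4919 (65.0%, 64.0 to 66.1) were overlapped by an ab21061 peak. Random placement gave means of 0.474% and 0.485%, so the overlaps were 134-fold above random in both directions. With random peaks kept in the same classes of distance to a gene end, the folds were 104 and 103. Neither random comparison takes account of open chromatin or of a control that both lists may have shared in peak calling. The overlaps formed 4853 shared regions, of which 4760 joined a single peak of each list.

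Overlap rose with the score. Between scores of 50 and 60, 31.7% of ab21061 and 32.4% of sc8558 peaks were overlapped. Between 80 and 100 the shares were 66.7% and 69.6%, and between 150 and 200 they were 96.7% and 97.8%. At 200 or more, 1042 of 1044 ab21061 peaks and 946 of 948 sc8558 peaks were overlapped. Across 4962 overlapping pairs the scores had a Spearman rho of 0.694 (0.678 to 0.712) and the widths of 0.687 (0.668 to 0.704). These correlations are across peaks, which are not independent replicates.

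**Figure D1:**
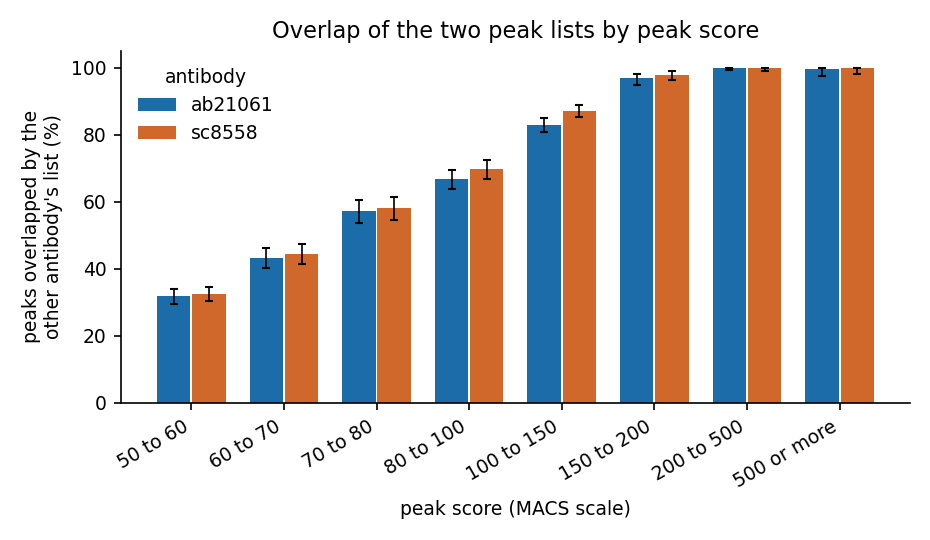
Share of peaks (%) overlapped by at least 1 bp of the other antibody's list, by class of the authors' peak score, for ab21061 (blue) and sc8558 (orange). Error bars are exact 95% intervals for counting error, and the shares rise from 31.7% and 32.4% in the lowest class to 99.5% and 100% at scores of 500 or more.

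The highest-ranking shared regions lay in varied settings. The region ranked first, on chromosome 17 from 26880157 to 26886028, had a score of 3100 in both lists, tied with the second, and peak width set their order. It lay 411 kb from the nearest gene end, that of WSB1, inside a stretch without annotated genes, as did another at 26619030 to 26620491. The second lay on chromosome 5 from 134922951 to 134928759 within PCBD2 and over copies of mitochondrial genes, again at 3100 in both. Another of the 10, on chromosome 1 from 628769 to 635247, also covered mitochondrial copies, within LOC102724250. A region on chromosome 1 from 95071441 to 95073496 lay 0.482 kb from an end of ALG14, a subunit of the enzyme that adds a sugar early in N-glycosylation, with scores of 2475 and 2645. A region on chromosome 12 from 95215734 to 95217758 lay 0.721 kb from an end of FGD6, with scores of 1601 and 1490. A region within WWP2, a ubiquitin ligase gene, scored 2366 and 2365 on chromosome 16 from 69795687 to 69800020. The remaining 3 were nearest to TMCO5A, KCTD6 and RAD52, at 89.5, 20.8 and 94.2 kb, and the last of these lay inside ERC1.

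Peaks without overlap had lower scores. The highest of ab21061, on chromosome 11 from 94233351 to 94239972, scored 846.75 and was nearest to PANX1, which encodes a membrane channel, at 54.7 kb. The nearest sc8558 peak was 168 kb away. Others were a peak nearest to ZNF37A, although 1818 kb from it, with a score of 211.67 and an sc8558 peak 0.709 kb away, and a peak inside SGK1, a kinase gene, with a score of 177.66. For sc8558 the highest scored 447.95 on chromosome 22 from 12177577 to 12178946, 3350 kb from OR11H1. It was followed by peaks nearest to DACH1, IFNGR1, TP53BP2 and LOC124901649, with scores of 212.67, 195.97, 195.25 and 180.41, the last lying 2559 kb from the named gene. The nearest ab21061 peaks were 1.29, 5.58, 80.3 and 2.88 kb away, so several of these peaks lay beside a peak of the other list.

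Peaks of both antibodies lay near ends of protein-coding genes more often than random placement gave. Within 1 kb of an end lay 591 ab21061 peaks (7.69%, 7.10 to 8.31) and 614 sc8558 peaks (8.12%, 7.51 to 8.76), against random means of 2.56% for both, so the shares were 3.00-fold and 3.18-fold above random. Most peaks were distal, with median distances of 36.2 and 33.1 kb. Over 100 kb from any end lay 29.6% and 28.5%, against 39.7% and 39.6% at random. Midpoints lay inside protein-coding genes for 44.1% and 44.7% of peaks, where random sets ranged from 40.9 to 44.5% and from 41.1 to 44.5%. Assembly gaps were not excluded from random placement. Random shares near and inside genes may therefore be too low, and those over 100 kb too high. Against this background the share inside genes was within the random range for ab21061 and above it for sc8558. Both shares lay close to the random maxima, and their intervals overlapped (42.9 to 45.2% and 43.6 to 45.8%). These calls therefore do not set the antibodies apart. These calls depended on the peaks taken: without the longest gene-free stretches the shares were 50.7% and 51.0%, above random maxima of 46.5% and 46.2%, and at a score of 100 or more they were 46.2% (above a maximum of 45.9%) and 45.1% (within a maximum of 45.4%).

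**Figure D2:**
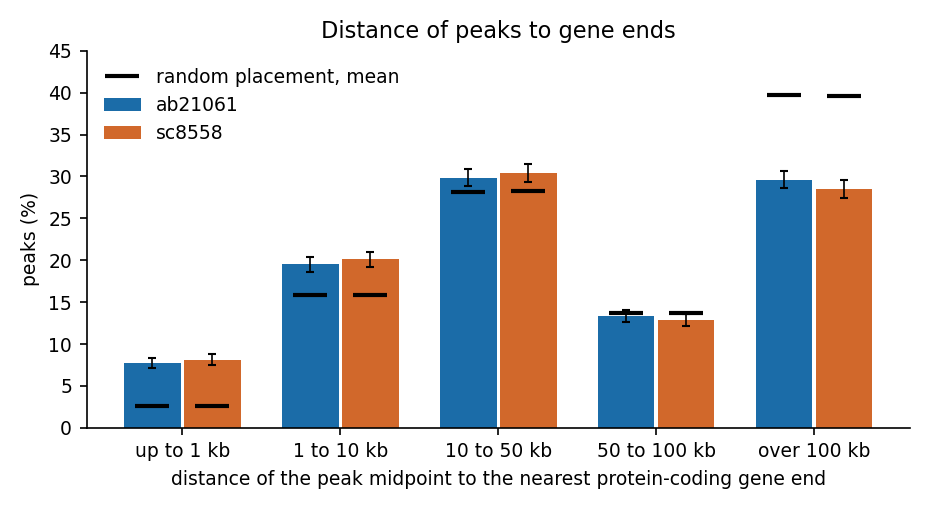
Share of peaks (%) by distance of the midpoint to the nearest end of a protein-coding gene, for ab21061 (blue) and sc8558 (orange), with exact 95% intervals. Black lines are means of random placement, which both antibodies exceed 3.00-fold and 3.18-fold up to 1 kb and fall below over 100 kb.

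Peaks found with both antibodies were compared with those found with a single antibody. In the ab21061 list 8.62% of overlapped peaks and 6.06% of the others lay within 1 kb of a gene end, a difference of 2.56 percentage points (1.35 to 3.73). In the sc8558 list the shares were 8.48% and 7.45%, and the interval of the difference, 1.02 points (-0.276 to 2.27), included 0. At a score of 100 or more in both lists the sc8558 difference changed sign, to -0.247 points (-2.80 to 2.06), again with 0 in the interval. Overlapped peaks had median scores of 108 and 106 against 62.4 and 61.7, and median widths of 844 and 803 bp against 663 and 641 bp.

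The GFI1 gene itself, on chromosome 1 from 92473043 to 92486925, was overlapped by 4 peaks of ab21061 and 5 of sc8558. All 4 ab21061 peaks had an sc8558 counterpart. Near the lower coordinate, a shared region from 92473100 to 92474496 scored 107.82 with ab21061 and 171.31 with sc8558. The peaks across the other end scored 132.03 and 85.27 and were also shared. The sc8558 peak without overlap, from 92474801 to 92475384, scored 60.51. GFI1B, the paralog of GFI1, was overlapped on chromosome 9 by 2 peaks of each list, all of them shared. Beyond that gene, a shared pair from 133019211 scored 474.34 and 263.94. In RARA, the retinoic acid receptor gene on chromosome 17, each list had a peak in a shared region from 40325448 to 40326952, scoring 85.8 and 70.08. PML had 0 ab21061 peaks within 50 kb and 1 sc8558 peak, with a score of 54.17.

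**Figure D3:**
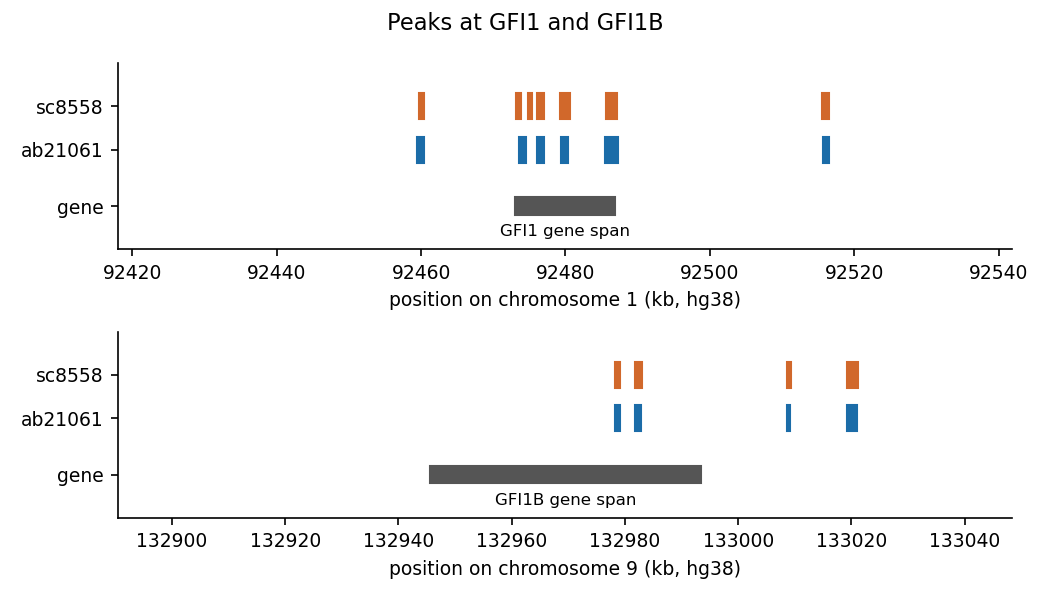
Map of peaks around GFI1 (chromosome 1) and GFI1B (chromosome 9), drawn to scale in kb on hg38, with ab21061 in blue, sc8558 in orange and the gene span in grey. GFI1 is overlapped by 4 and 5 peaks and GFI1B by 2 peaks of each antibody.

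Myeloid transcription factor genes and monocyte and macrophage genes had shared regions at their ends more often than random lists. Among the 38 myeloid transcription factor genes 5 had a shared region within 1 kb, against a random mean of 0.873 and a random range up to 4. The 5 genes included ZEB2 (scores 211.09 and 174.3), KLF2 (146.8 and 126.52), GFI1 and FOS (123.27 and 73.24), which encodes a component of AP-1. JUN, the fifth, was named after its values were seen, with scores of 64.88 and 58.18. Among 24 monocyte and macrophage genes there were 4, against a mean of 0.552 and a range up to 3. The 4 genes were CD86, a costimulatory ligand (155.64 and 165.66), CCR2, a chemokine receptor (96.16 and 162.85), MNDA (80.22 and 192.56) and CD163, a scavenger receptor (76.51 and 161.03). Within 1 kb at a score of 100 or more in both lists no list stood apart. The counts were 3 and 1 for these lists, still above the random means of 0.422 and 0.254. Fewer genes had a shared region there, 215 of 20037 against 456. The myeloid transcription factor count also fell within the random range with ab21061 peaks alone (4 genes, mean 1.21). So did the monocyte and macrophage count within 5 kb of gene ends (5 genes, mean 1.37). Over gene spans with 10 kb on either side the latter was 8 genes, also within the range (means 3.10 with matched lengths and 3.06 with moved lists).

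Olfactory receptor and zinc-finger genes had fewer shared regions than random lists. Of 390 olfactory receptor genes 1 had a shared region, OR52W1, against a mean of 8.90. Of 509 ZNF genes 3 did, ZNF516, ZNF546 and ZNF114, against 11.6. The olfactory count fell within the random range when lists were matched on gene length (1 against a mean of 6.1994). The ZNF count did so when lists were moved along the gene order (3 against 11.6). Those ranges began at 1 and 3, so each count lay at the lower edge of its range and stayed below the mean.

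The other 12 lists lay within the range of random lists. For each of these the range began at 0, so a low count, or none, could not stand apart. Of 34 neutrophil granule genes 2 had a shared region within 1 kb, S100A12 (155.07 and 110.07), a calcium-binding protein gene, and LYZ, the lysozyme gene (138.89 and 71.07). Of 30 reported GFI1 targets only GFI1 did, against a mean of 0.675. None of 32 genes linked to retinoic acid or PML-RARA did (mean 0.743), nor of 26 corepressor partners of GFI1 (0.607), 27 lymphoid genes (0.635), 35 cell cycle genes (0.794) or 24 liver and neuron genes (0.548). A single gene did in the stem cell and HOX list of 28 (SOX4, 451.49 and 620.96), the erythroid and megakaryocytic list of 25 (HBB, the beta-globin gene) and the apoptosis list of 30 (TNFRSF10B, a TRAIL receptor gene). Ribosomal protein genes had 5 of 83, RPL39, RPL24, RPL23A and RPL23 among them, against 1.92. Histone genes had 3 of 69, H3C6, H2BC4 and H4C2, against 1.57.

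**Figure D4:**
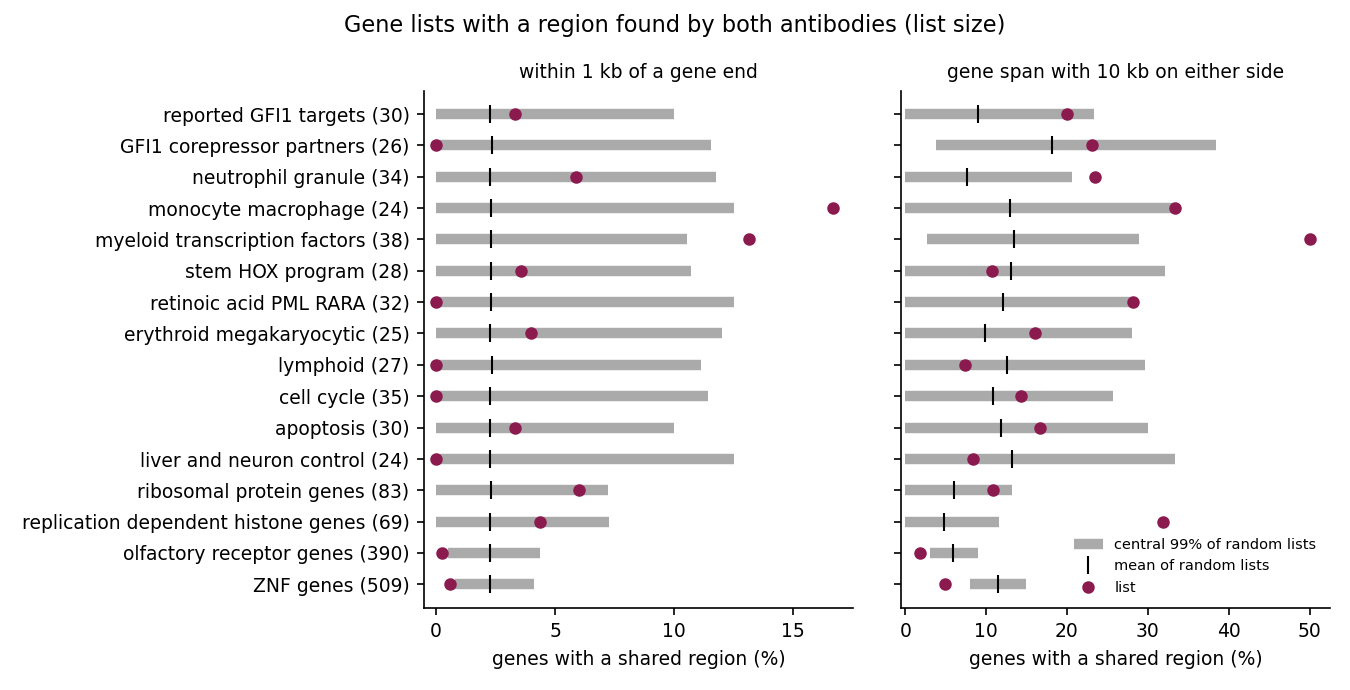
Share of genes (%) in each list with a region found by both antibodies, within 1 kb of an end (left) and over the gene span with 10 kb on either side with random lists matched on gene length (right, chosen after seeing the data). Points are the lists, grey bars the central 99% of 10000 random lists and ticks their means, with 5 of 38 and 19 of 38 myeloid transcription factor genes above the bars.

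**Figure D5:**
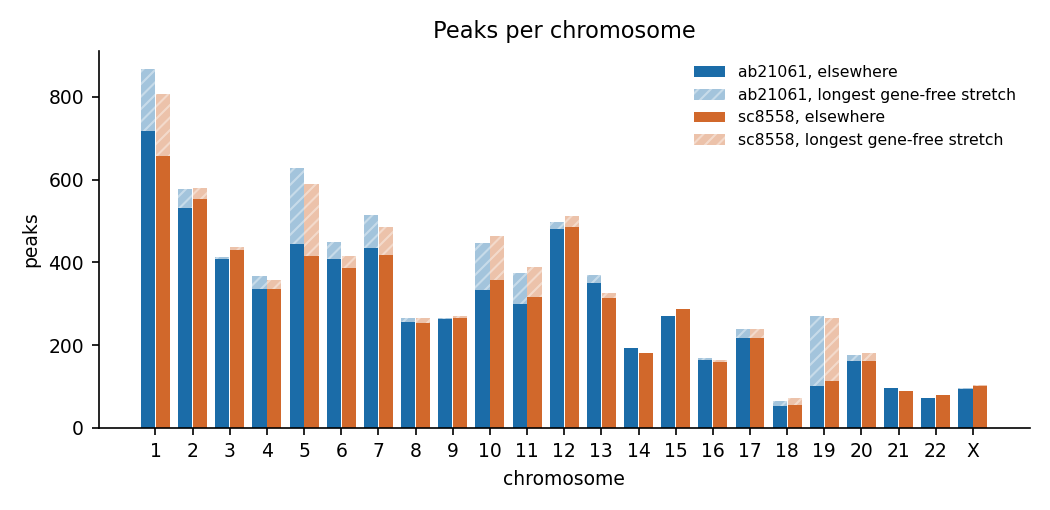
Number of peaks per chromosome for ab21061 (blue) and sc8558 (orange), with the hatched part lying in the longest stretch of each chromosome without an annotated gene. On chromosome 19 the stretch holds 168 of 270 and 152 of 265 peaks.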

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

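Alternatives that left out gene-free stretches, matched lists on gene length, moved lists along the gene order, used gene spans with 10 kb on either side, took each antibody alone, set high-scoring peaks against the full other list or took the share inside genes at a score of 100 or more were chosen after seeing the data. The cause of the changes was not tested, except where fewer peaks enter by construction. The 4 planned motif alternatives were not run, and lists without GC matching became the main ones. With 1 library per antibody, none was left out, and unknown depth limits any reading of peaks found with a single antibody.

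At a score of 100 or more, there were 2901 and 2831 peaks. Overlap for ab21061 and sc8558 was 70.3 and 72.2% at that score in both lists, 70.5 and 70.8% with equal numbers of top peaks, 60.7 and 61.7% when 50% of both peaks had to overlap, 62.5 and 63.6% with midpoints within 500 bp, and 91.6 and 93.5% for high-scoring peaks against the full other list. All stayed far above random placement.

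The shares near gene ends were 13.3 and 13.9% within 2.5 kb (random means 5.93% for both) and 9.91 and 10.4% for any overlap with the windows (3.59 and 3.55%). For ends of all gene types they were 13.7 and 14.7% (6.39% for both). In these 3 settings the random shares rose as well, since more of the genome counts as near an end. The shares were 8.76 and 9.47% at a score of 100 or more (2.56 and 2.58%), and 8.84 and 9.26% without the gene-free stretches (2.57 and 2.61%). Inside genes lay 50.7 and 51.0% without those stretches (random means 44.8 and 44.9%), and 46.2 and 45.1% at a score of 100 or more (42.9 and 42.8%). The difference near gene ends between shared and single-antibody peaks stayed above 0 for ab21061 (2.13 to 3.09 points, no interval including 0), whereas for sc8558 it ran from -0.247 to 1.18 and every interval included 0. For scores, rho was 0.733 with 50% overlap and 0.758 at scores of 100 or more. For widths it was 0.752 and 0.723, and 0.664 without the stretches.

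The number of lists apart was 4, and 0 within 1 kb at a score of 100 or more in both lists. There the myeloid transcription factor count was 3 (mean 0.422), the monocyte and macrophage count 1 (0.254), the olfactory count 1 (4.19) and the ZNF count 1 (5.47). Each was within the range of random lists, but on the same side of the mean as in the main setting. The range began at 0 for the olfactory list and at 1 for the ZNF list. Other counts that fell within it were 4 myeloid transcription factor genes with ab21061 alone, 5 monocyte and macrophage genes within 5 kb (also with lists moved along the gene order) and 8 over gene spans under both comparisons, 1 olfactory receptor gene with matched lengths and 3 ZNF genes with moved lists. Lists that newly stood apart were neutrophil granule genes (8 over gene spans with matched lengths), ribosomal protein genes (8 with ab21061 alone) and histone genes (10 within 5 kb, though within the range when lists were moved along the gene order, and 22 over gene spans under both comparisons).

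Counts that crossed the random mean did so in lists within the random range in both settings. From below to above went corepressor partners (3 within 5 kb, also with moved lists, 6 over gene spans under both comparisons, and 2 with sc8558 alone), retinoic acid and PML-RARA genes (4 within 5 kb, also with moved lists, and 9 over gene spans under both comparisons), cell cycle genes (2 within 5 kb, also with moved lists, and 5 over gene spans under both comparisons) and lymphoid genes (1 with sc8558 alone). At a score of 100 or more over gene spans, also chosen after seeing the data, 4 lists stood apart under both comparisons: 14 myeloid transcription factor genes and 16 histone genes above, and olfactory receptor and ZNF genes below. There the monocyte and macrophage count of 4 was within the range, and corepressor partners (3) and retinoic acid and PML-RARA genes (3) were above the random mean but within the range. From above to below went stem cell and HOX genes (1 within 5 kb, also with moved lists, and 3 over gene spans under both comparisons), erythroid and megakaryocytic genes (1 within 5 kb, also with moved lists, and 0 at a score of 100 or more) and ribosomal protein genes (9 over gene spans with moved lists).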

Other observations

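The tests of explanations in this part, and the sets of genes and regions described here, were chosen after the results were seen. Taken over gene spans with 10 kb on either side, 19 of 38 myeloid transcription factor genes held a shared region, against means of 5.09 for random lists matched on gene length and 4.83 for lists moved along the gene order. RUNX1 (scores 726.25 and 672.47), MYB (566.47 and 699.07), KLF6 (395.88 and 461.28) and IKZF1 (225.27 and 318.58) were among them, and ELF1 alone held 8 regions. Neutrophil genes with a shared region included MPO, CYBB and FCN1, 8 of 34 in all, which stood apart with matched lengths but not with moved lists. Of 69 histone genes 22 had a shared region in this window, above both comparisons, but neighbouring genes share them and only 8 distinct regions lie behind the count. Of 30 reported GFI1 targets 6 had a shared region in this window, within the range of both comparisons (means 2.72 with matched lengths and 3.85 with moved lists). Among them ID1 had a shared region 2394 bp from its nearer end with scores of 486.25 and 499.69.

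Some genes and windows outside the gene-free stretches held many shared regions. MAML2 held 10 where its length alone would give 0.631, FNDC3B 8, and ARHGAP26 and ITPR2 7 each. The densest window of 1 Mb, on chromosome 4 from 40000001 to 41000000, held 18 and includes RHOH and RBM47. Genes for tRNAs were overlapped more often than at random, 36 of 443 by ab21061 and 27 by sc8558 against means of 1.23 and 0.965, with 18 overlapped by both. For small nuclear RNA genes the counts were 15 and 19 of 154, against 0.465 and 0.43, with 13 in both. The distinct peaks behind these counts were not counted, and neighbouring genes may share them. No such excess was seen for miRNA genes (4 and 5 of 1913, against 4.85 and 4.67) or lncRNA genes (1008 and 1015 of 18303, against 1079 and 1058), and snoRNA genes (7 and 3 of 1199, against 3.04 and 3.06) stayed below the random maxima of 12 and 8.

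Copies of mitochondrial genes in the nuclear genome carried 10 ab21061 and 11 sc8558 peaks, against means of 1.39 each at random, with median scores of 378.26 and 658.58. This set of 487 genes includes the MTRNR2L genes, which were added after their scores had been seen. Without them, 474 genes carried 6 and 7 peaks, with median scores of 166 and 125, where the highest of the random sets had 6 and 5. Of the 50 highest-ranking peaks of ab21061 and sc8558, 4 and 5 lay over the wider set, and 6 and 5 lay in the longest gene-free stretches. No explanation was tested for the peaks over mitochondrial copies, and no control library was analysed.

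Of the peaks found with a single antibody, 2 of 2791 with ab21061 and 2 of 2643 with sc8558 had a score of 200 or more. They were nearest to PANX1 (846.75) and ZNF37A (211.67) with ab21061, and to OR11H1 (447.95) and DACH1 (212.67) with sc8558. No explanation was tested for the peaks found with a single antibody, and depth and the control used were not examined.

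The longest gene-free stretches held 1000 ab21061 peaks (13.0%) and 932 sc8558 peaks (12.3%), 2.46-fold and 2.34-fold above random placement. The peaks were unevenly spread: 61.6% and 62.4% of them lay on chromosomes 1, 5, 10 and 19, whereas the stretch of chromosome 9, 17.7 Mb long, held 3 and 4. Assembly gaps were not excluded from random placement. Low counts may therefore reflect missing sequence, and the folds over random placement may be too low. Peaks per Mb of stretch followed each other between the antibodies across chromosomes (rho 0.988), so both lists showed a similar pattern. This rho alone cannot decide against a signal of a single antibody, since stretches without assembled sequence would be empty in both lists. The overlap within the stretches argues against it for the overlapped peaks. There 612 of 1000 ab21061 peaks (61.2%) and 609 of 932 sc8558 peaks (65.3%) were overlapped by the other list. Without the stretches the shares were 64.1% and 65.0%. The stretches of chromosomes 14, 21 and 22 held 0 peaks in either list. Repeat sequence piled up on the assembly cannot be told apart from binding, since 61.2% of these ab21061 peaks were overlapped in the other list and both explanations allow that without a control library. No biological explanation was tested.

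The count of myeloid transcription factor genes at 1 kb was reached in 0.150% of cases with length-matched lists and 0.170% with moved lists, when the list itself is counted as a case. Over gene spans no random list reached 19, the highest having 14 and 13, which gives 0.0100% by the same count, the smallest that 10000 lists can give, so gene length and the clustering of genes are not the whole cause. Open chromatin of active genes may still account for the count. Of 83 ribosomal protein genes 5 had a shared region within 1 kb, above their mean but within the random range. They stood apart with ab21061 alone. Over gene spans 9 had a region, within the range of both comparisons. That was above the mean of length-matched lists (4.96) and below that of moved lists (10.6). At 1 kb the ribosomal comparison could not argue against open chromatin, since its random range began at 0. Weak peaks are not decided at 1 kb. There 3 members at a score of 100 or more were above the random mean of 0.422 but within the range, which reached 3. Weak peaks do not stay open over gene spans, where 14 members at that score exceeded every random list (highest 10 and 9). Binding of GFI1 at these genes is a hypothesis that these 2 lists cannot separate from open chromatin or from a control that both may have shared. Nor can they settle the conflict between the antibody labels and the protocol, which names the PML/RARα fusion protein.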
